A study of Homo sapiens with 2 samples.

How the data were processed

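Total RNA of 2 untreated human small cell lung cancer cell lines, H446 and SHP77, was sequenced for circular RNA, with 1 library per line. Per the labels' protocols, cells were grown in medium with 10% serum, ribosomal RNA was depleted, the RNA was digested with RNase R and fragmented to about 200 bp, libraries were made with a NEBNext Ultra RNA kit, and paired-end reads of 150 bp were sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, the tools named are bcl2fastq, Trimmomatic 0.36, FastQC, BWA and TopHat, and the builds GRCh37 and hg19. The program that called circRNAs, its filters and the annotation behind the host gene names are not given in the sources used here.

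For each circRNA the authors deposited its position, a host gene name, the count of back-splice reads and an RPM value. Per the file headers these are the columns count and RPM, and the count values are whole numbers from 2 upward. The deposited RPM equals the count scaled by the total count of its file, to the rounding of the file (largest difference 0.00498), so RPM carries no information beyond the count. Only circRNAs with at least 2 reads were listed, so a circRNA that is not listed may have 0 or 1 read or may have been removed by a step that is not described. Linear RNA of the host genes was not analysed here, so a difference in circRNA level is not separated from a difference in transcription of its gene. RNase R digestion and amplification change the yield of circRNAs, and with 1 library per line their variation was not measured.

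Positions are given as in the files, on hg19. The files give no strand, and the host gene is the one named there, which is uncertain where genes overlap or lie antisense. Exon, intron and untranslated region positions were not assigned, because the annotation at hand is on GRCh38. A gene table of the GRCh38.p14 assembly was used for names, synonyms and gene classes only, and matched 99.5% of H446 and 99.4% of SHP77 host names. Protein-coding genes were 98.1% of host genes in H446 and 97.3% in SHP77. Genes of the Y chromosome were left out.

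The design, gene lists, named-gene rule and alternatives were fixed before the data were examined, except where the text says otherwise. No replicate-based model could be fitted. The main measure was the ratio of RPM, that is of back-splice reads scaled to the total of back-splice reads, SHP77 over H446, with an exact 95% Clopper-Pearson interval conditional on the sum of reads. Reads were compared by two-sided Fisher's exact test with Benjamini-Hochberg adjustment, over circRNAs with at least 10 reads and host genes with at least 20 reads over both libraries. A difference was counted at an adjusted p under 0.05 and at least 2-fold. Such a test compares 2 libraries, not 2 conditions. Items that missed either criterion are called not different, also where only the 2-fold minimum was missed. Against a library where a circRNA was not listed, the fold was computed against a floor of 3 reads, which is 14.0 RPM in H446 and 17.2 RPM in SHP77, and is given as a bound. For a host gene not listed in 1 library, each junction may hold 1 unlisted read, so the floor was 1 read for each junction listed in the other library and no fewer than 3 reads, a rule chosen after seeing the data. The floor assumes that no step removed the circRNA, and leaves out junctions listed in neither library and, above 3 junctions, counting error. Counting error of the reads in the listing library is left out throughout, so such a bound is a fold against the floor and not a 95% limit. At the floor of 3 reads the exact 95% lower limit can be lower, as for the SOBP junction (147-fold against 181-fold).

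For 18 gene lists, the text gives the number of members that differed over all host genes tested and with adjustment over the list alone, the median log2 ratio with 0.5 reads added to each library, and the percentile of that median among 10000 random lists matched on decile of reads. The lists covered hosts described in small cell lung cancer, widely described circRNA hosts, neuroendocrine and neuronal, mesenchymal and non-neuroendocrine, and epithelial genes, the Hippo, Notch and WNT pathways, DNA repair and platinum response, drug transport, apoptosis, chromatin modifiers, cell cycle and MYC, regulators of back-splicing, receptor kinase, PI3K and MAPK signalling, region 8q24, and haematopoietic and endothelial markers of other cell types. FLI1, ESRP1 and CDR1 of the first list were not analysed here. Within host genes with at least 2 circRNAs and at least 20 reads in each library, the share of the leading junction was compared by Fisher's exact test. Shares of reads per chromosome carry exact intervals.

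The text names the 5 most abundant circRNAs of each library, the 8 circRNAs and 10 host genes in each direction whose interval bound nearest to 1 was farthest from it, up to 4 measured members of each list with most reads and the members that differed, every measured member of the list described in small cell lung cancer, and the 5 host genes with the lowest adjusted p for junction use. Some genes covered by this rule are not reported here. Genes named in the closing observations were chosen after their values were seen.

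Before use, the procedure was tested on simulated data with 200 changed items drawn at the real depths. Counts were Poisson draws from the pooled profile of both libraries, so their only noise was counting error, which the exact test covers. The shares of unchanged items called below therefore give no error rate for variation of preparation or amplification. At the level of host genes (2836 tested), 38.0% of 2-fold, 92.0% of 4-fold and 100% of 8-fold and 16-fold changes were called, with 0.076% of 2636 unchanged genes called. For circRNAs (7053 tested), 4.5% of 2-fold, 47.9% of 4-fold, 83.3% of 8-fold and 94.0% of 16-fold changes were called, with 0.219% of 6863 unchanged ones called. A true 2-fold difference in a circRNA was therefore mostly missed by this procedure, which also requires a measured difference of at least 2-fold, and the effects of depth and of that minimum were not separated.

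The alternatives were scaling by edgeR 4.0.16 TMM factors or DESeq2 1.42.0 size factors (R 4.3.3), which were used for factors only, the authors' RPM, other read minimums, a 4-fold minimum, exclusion of circRNAs over 100 kb, only the leading junction of each host gene, 2 reads added in place of 0.5, thinning of the deeper library over 100 draws, junction positions matched within 5 bases, and exclusion of the 20 most abundant circRNAs. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.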

Results

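Circular RNAs, which are closed by a back-splice junction that joins the end of an exon to the start of the same or an earlier exon, were profiled in 2 human small cell lung cancer cell lines, each represented by 1 library. The labels describe H446 as chemosensitive and as derived from a pleural effusion, a metastatic site. They describe SHP77 as chemoresistant and as derived from a primary lung tumour. Both lines were untreated. The libraries were made from total RNA depleted of ribosomal RNA and digested with RNase R, an exonuclease that degrades linear RNA. The H446 library held 214758 back-splice reads over 12473 circRNAs of 4398 host genes. The SHP77 library held 174872 back-splice reads over 11123 circRNAs of 4330 host genes. One read was worth 4.66 RPM in H446 and 5.72 RPM in SHP77, where RPM is the files' scaling of reads to the total of back-splice reads in the library. There were no replicates, so every difference below is between these 2 libraries and has no replicate check. It cannot be assigned to the response to chemotherapy, the site of origin or any other property in which the lines differ. Intervals and floors cover at most counting error, because amplified reads without molecular identifiers are not independent molecules.

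ASPH, which encodes aspartate beta-hydroxylase, gave the most abundant circRNA of both libraries, from a junction at chromosome 8, 62593527 to 62596747 (hg19). This circRNA took 1.78% of back-splice reads in H446 (exact 95% interval 1.72 to 1.84%) and 0.797% in SHP77 (0.755 to 0.839%). It was 2.23-fold higher in the H446 library. The next 4 in H446 came from CAMSAP1, which encodes a protein that binds microtubule minus ends, from CEP72, which encodes a centrosomal protein, from CDYL, which encodes a chromodomain protein, and from HIPK3, which encodes a protein kinase. The CAMSAP1 junction (chromosome 9, 138773479 to 138774924) had 2336 reads in H446 and 730 in SHP77, a 2.61-fold difference. The CEP72 junction (chromosome 5, 619105 to 620376) had 1759 and 34 reads and was 42.1-fold higher in H446 (95% interval 30.0 to 61.0). The HIPK3 junction (chromosome 11, 33307959 to 33309057) had 1164 and 401 reads, 2.36-fold higher in H446. The CDYL junction (chromosome 6, 4891947 to 4892613) had 1326 and 594 reads, a ratio of 1.82 that stayed under the required 2-fold.

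In SHP77, ASPH was followed by PDE4B, which encodes a cyclic AMP phosphodiesterase. Its junction (chromosome 1, 66378928 to 66384518) had 1210 reads in SHP77 and 2 in H446, a 743-fold difference (95% interval 205 to 6142). GSE1 (chromosome 16, 85667520 to 85667738) had 1171 reads in SHP77 and 243 in H446, a 5.92-fold difference. SETD3, which encodes a histidine methyltransferase of actin, gave a circRNA (chromosome 14, 99924616 to 99932150) with 1092 reads in SHP77 and 469 in H446, 2.86-fold higher in SHP77. The BANP junction (chromosome 16, 88061089 to 88071617) had 962 and 511 reads and was 2.31-fold higher in SHP77. Beyond these, both catalogues had a similar make-up. The median circRNA had 6 reads in each library, 315 circRNAs in H446 and 249 in SHP77 had at least 100 reads, and the top 100 circRNAs took 21.3% of reads in each. The median span between junction positions was 7886 bp in H446 and 6755 bp in SHP77. SMARCC1 had the most junctions in H446, 29, and BIRC6 the most in SHP77, 25.

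The first comparison asked how far the catalogues of the 2 lines coincide. Of 17995 circRNAs listed in either library, 5601 (31.1%) had identical junction positions in both. They were 44.9% of the H446 catalogue and 50.4% of the SHP77 catalogue, and held 74.4% of H446 reads and 75.6% of SHP77 reads. CDYL2, FNDC3B, KCNH5 and UBE3A gave the most abundant H446 circRNAs that were not listed in SHP77, and SOBP, RPH3AL and ZNF208 were among the hosts of those of SHP77 that were not listed in H446. In all, 28 of the 315 H446 circRNAs with at least 100 reads, and 30 of the 249 in SHP77, were not listed in the other library. Host genes were shared more widely, with 3157 of 5571 listed in both. Across the 5601 shared circRNAs, the Spearman correlation of the reads was 0.56. This is a correlation across circRNAs, which are not independent replicates. After the deeper H446 library was thinned to the SHP77 total, 5460 ± 9.75 circRNAs (SD over 100 draws) were shared. A circRNA that is not listed had fewer than 2 reads or was left out by a step that the sources used here do not describe.

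The second comparison asked which circRNAs differ between the line labelled chemoresistant and the line labelled chemosensitive. The junction of PDE4B had the largest difference toward SHP77 by the interval bound nearest to 1. Junctions that followed included those of SOBP (chromosome 6, 107824861 to 107827631), RPH3AL (chromosome 17, 169211 to 177370) and ZNF208 (chromosome 19, 22157531 to 22171711). Toward H446, the largest differences were at junctions of CDYL2 (chromosome 16, 80718435 to 80719026), FNDC3B (chromosome 3, 171830242 to 171851336), the potassium channel gene KCNH5 (chromosome 14, 63447590 to 63483672) and the ubiquitin ligase gene UBE3A (chromosome 15, 25650608 to 25657118). The SOBP junction had 443 reads in SHP77 and was at least 181-fold higher there, taking the floor of 3 reads for a circRNA that is not listed. The CDYL2 junction had 627 reads in H446 and was at least 170.2-fold higher there.

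Further junctions higher in SHP77 belonged to RAPGEF5 (chromosome 7, 22330794 to 22357656), NBEAP1 (chromosome 15, 20874797 to 20876597) and HGS (chromosome 17, 79660684 to 79661883). They had 227, 219 and 218 reads in SHP77 and were not listed in H446, so that the RAPGEF5 junction was at least 92.9-fold higher and the HGS junction at least 89.2-fold higher in SHP77. The other 4 higher in H446 belonged to USP25 (chromosome 21, 17135210 to 17138460), PTK2 (chromosome 8, 141828376 to 141900868), PRKAR1B (chromosome 7, 716866 to 751164) and DGKD (chromosome 2, 234296903 to 234299129). They had 236, 221, 220 and 197 reads in H446 and none listed in SHP77, with bounds from at least 64.1-fold for USP25 to at least 53.5-fold for DGKD. The host genes FNDC3B, PTK2, PRKAR1B and DGKD were still listed in both libraries through other junctions.

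Over all circRNAs, 6973 had at least 10 reads over both libraries and were tested. By a two-sided Fisher's exact test on the reads with Benjamini-Hochberg adjustment and a 2-fold minimum, 1712 were higher in the SHP77 library and 1990 higher in the H446 library, and 3271 were not different. Of the 1712 higher in SHP77, 975 were not listed in H446, and of the 1990 higher in H446, 1295 were not listed in SHP77. With only circRNAs listed in both libraries, an alternative chosen after seeing the data, 662 of 4703 were higher in SHP77 and 626 higher in H446. The test compares 2 libraries, not 2 conditions.

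The third comparison summed back-splice reads over each host gene. For a host gene that is not listed in 1 library, the floor was 1 read for each of its junctions listed in the other library and no fewer than 3 reads. PDE4B had 1254 reads in SHP77 and 2 in H446, a 770.0-fold difference (95% interval 213 to 6365). SOBP, CNKSR3, a scaffold protein gene, RAPGEF5, a Rap guanine nucleotide exchange factor gene, ABCA13, of the ATP-binding cassette family, DGKB, a diacylglycerol kinase gene, and HGS, an endosomal sorting gene, were not listed in H446. SOBP was at least 221-fold higher in SHP77, CNKSR3 at least 36.0-fold, RAPGEF5 at least 78.2-fold, ABCA13 at least 21.5-fold, DGKB at least 18.4-fold and HGS at least 101-fold. SPATA6 had 464 reads in SHP77 and 2 in H446, a 285-fold difference (78.4 to 2359.6). The long intergenic RNA LINC00355 and the zinc finger gene ZNF208 were at least 97.0-fold and 94.2-fold higher in SHP77.

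CDYL2, a chromodomain gene, led the host genes higher in H446, with 664 reads there and none listed in SHP77, at least 90.1-fold higher. DOCK1, a Rac exchange factor gene with 20 junctions in H446, was at least 14.1-fold higher, and the deubiquitinase gene USP25 at least 26.5-fold. The nuclear transport receptor gene RANBP17 was at least 16.8-fold higher and the kinase gene VRK2 at least 55.4-fold. MYO1E, a class I myosin gene, was at least 11.5-fold higher, SUCLG2, of the citric acid cycle, at least 31.6-fold, and the glypican gene GPC5 at least 26.1-fold. NRIP1, a nuclear receptor cofactor gene, and NPR3, a natriuretic peptide receptor gene, each with 1 junction, were at least 48.3-fold and 47.5-fold higher in H446.

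Of 2858 host genes with at least 20 reads over both libraries, 754 were higher in SHP77 and 788 higher in H446 by the same exact test, and 1316 were not different. At 4-fold or more there were 427 and 462. Among the calls, 213 host genes were not listed in H446 and 198 were not listed in SHP77. By the same test, 1894 of the 2858 had an unadjusted p under 0.05. Some host genes counted as not different missed only the 2-fold minimum.

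**Figure D1:**
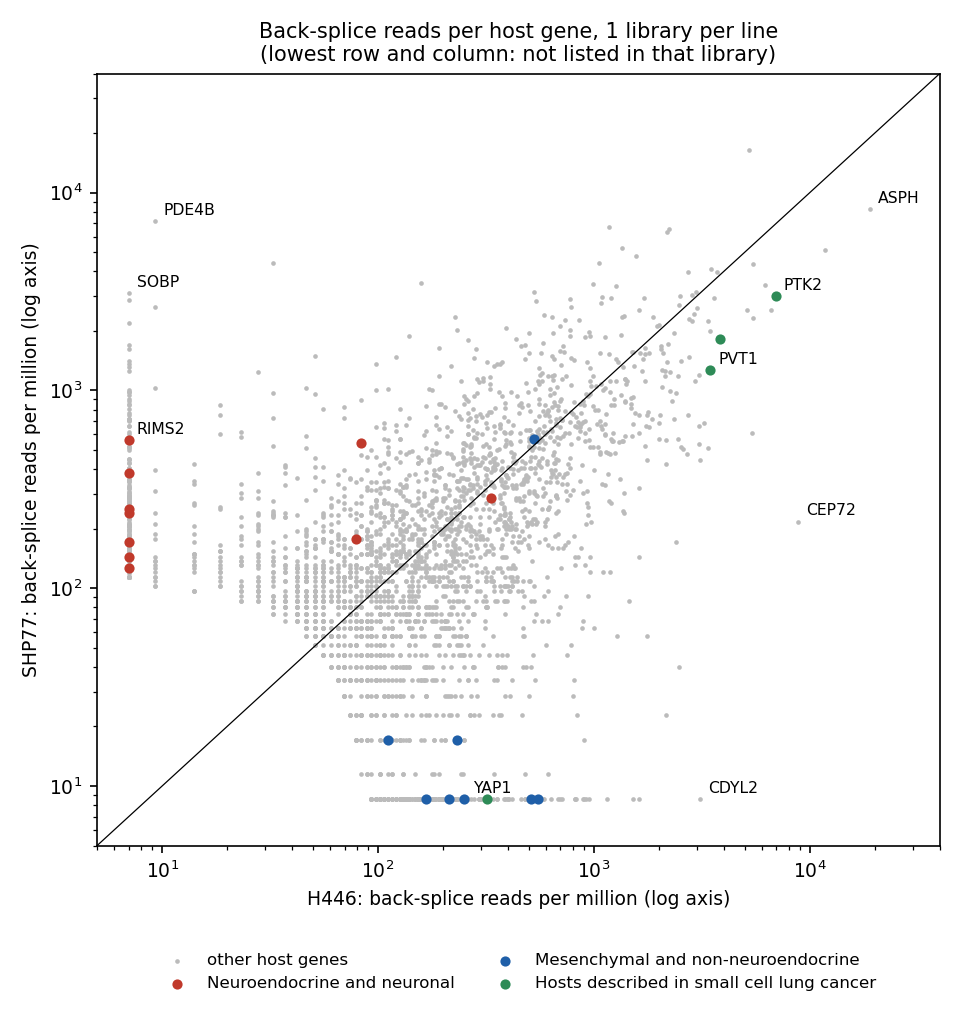
Back-splice reads in RPM of each host gene with at least 20 reads over both libraries, H446 on the horizontal and SHP77 on the vertical log axis, with 1 library per line, each point a host gene and the line marking equal values. Host genes not listed in a library are drawn in the lowest row or column, at a set position, where most neuroendocrine hosts lie for H446 and 5 of 8 mesenchymal hosts lie for SHP77.

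Neuroendocrine and neuronal host genes were higher in the SHP77 library. Of 10 measured members of this list, 9 were higher in SHP77, none was higher in H446 and 1 was not different. RIMS2, which encodes a presynaptic active zone protein, had 98 reads in SHP77 and was at least 15.0-fold higher. The potassium channel gene KCNB2 was at least 27.4-fold higher, SYT1, a calcium sensor of synaptic vesicles, at least 18.0-fold, the transcription factor gene MYT1L at least 12.3-fold, NRCAM at least 10.2-fold and DNM3 at least 6.75-fold. NBEA was 6.48-fold higher (95% interval 3.89 to 11.4) and UNC13B 2.24-fold higher (1.2 to 4.31) in SHP77. STXBP5L had 72 reads in H446 and 50 in SHP77 and was not different (adjusted p = 0.486, exact test). The list median was 6.10 on the log2 scale, and 3.49 with the 7 host genes not listed in H446 set to their bound, higher than in all 10000 random lists of the same size (percentile 100). With only the 3 members listed in both libraries, chosen after seeing the data, the median was 1.14 at percentile 91.5.

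Mesenchymal and non-neuroendocrine host genes were higher in the H446 library. Of 8 measured members, 7 were higher in H446, none was higher in SHP77 and 1 was not different. COL5A1, a fibrillar collagen gene, and FBN1, which encodes fibrillin, were at least 16-fold and 29.9-fold higher in H446. YAP1, the transcriptional coactivator of the Hippo pathway, had 54 reads in H446 and none listed in SHP77, at least 5.50-fold higher. AHNAK was at least 12.5-fold and the receptor kinase gene AXL at least 9.77-fold higher. MYOF was 13.6-fold higher (95% interval 4.38 to 68.0) and MET, the hepatocyte growth factor receptor gene, 6.51-fold higher (1.98 to 33.8) in H446. ZEB1 had 113 reads in H446 and 99 in SHP77 and was not different (adjusted p = 0.696, exact test). The list median was -6.07, and -3.42 with the 5 host genes not listed in SHP77 at their bound, lower than in all 10000 random lists (percentile 0). With only the 3 members listed in both libraries, chosen after seeing the data, the median was -2.51 at percentile 1.02. YAP1 also belongs to the Hippo list and MET to the receptor kinase list.

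Epithelial host genes went both ways. EPCAM had 54 reads in SHP77 and 2 in H446, a 33.2-fold difference (95% interval 8.75 to 281), and the polarity gene PARD3 was 3.87-fold higher in SHP77. The tight junction gene TJP1 was 2.08-fold higher in H446, a call lost with only the leading junction. The median of these 3 members was 1.94, at percentile 96.2 of random lists.

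**Figure D2:**
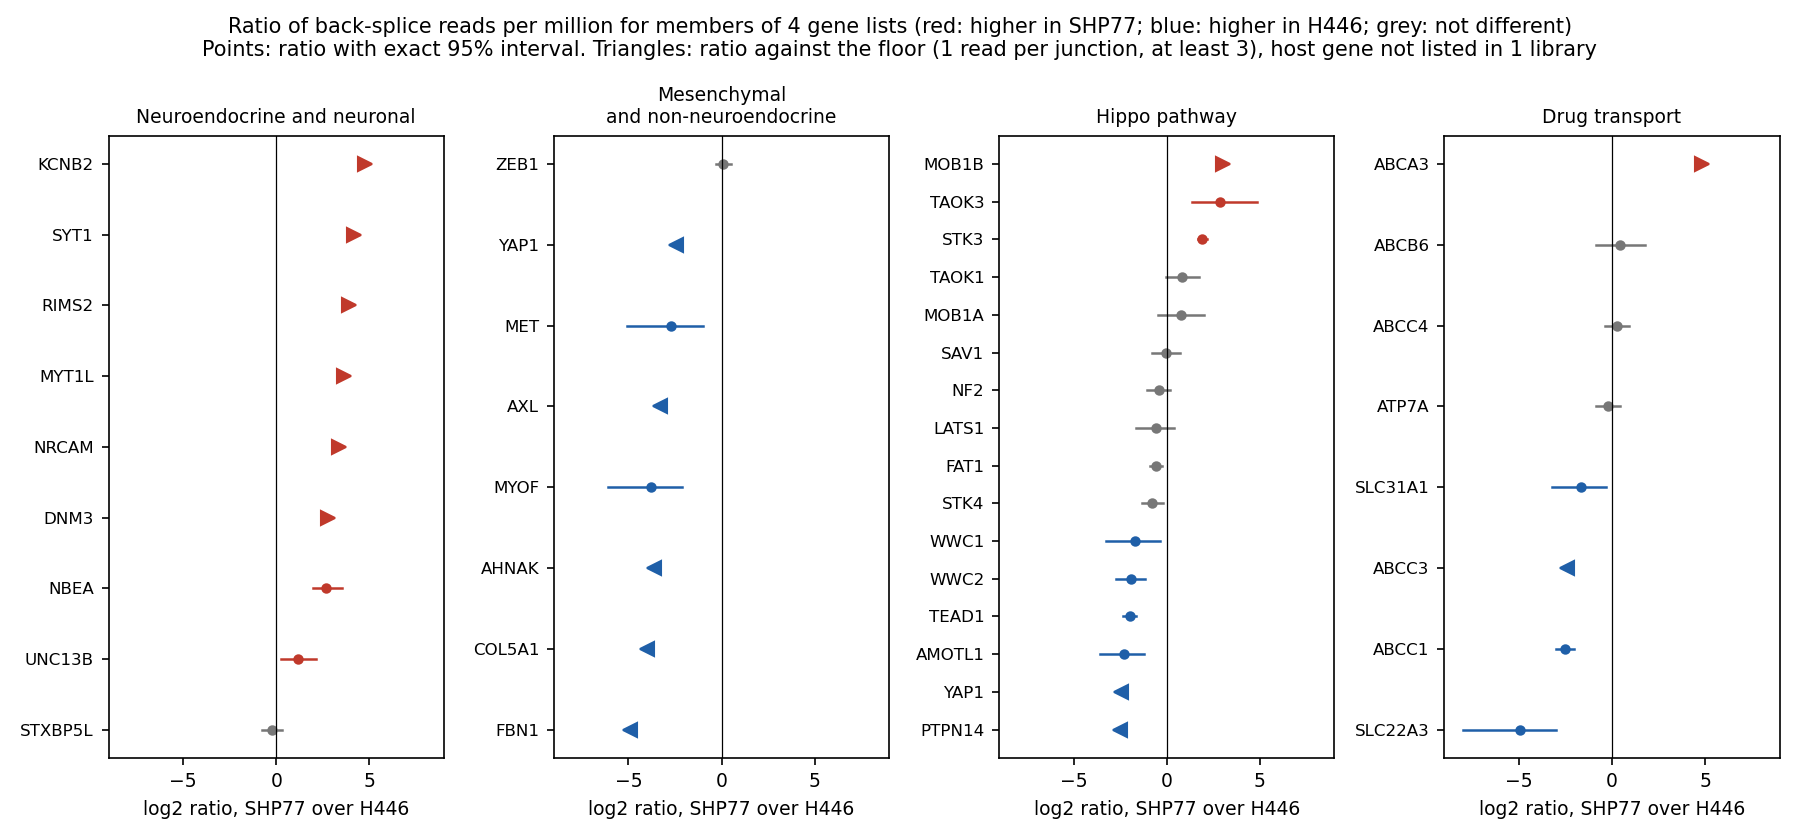
Log2 ratio of back-splice reads in RPM, SHP77 over H446, for measured members of 4 gene lists, with 1 library per line. Points carry the exact 95% interval for counting error, and triangles mark the ratio against the floor for host genes not listed in 1 library. The neuroendocrine list lies to the right except for STXBP5L, and the mesenchymal list to the left except for ZEB1.

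All 4 measured host genes of the list described in small cell lung cancer were higher in the H446 library. PVT1, a long non-coding RNA gene next to MYC, was 2.71-fold higher (95% interval 2.33 to 3.16), PTK2, which encodes focal adhesion kinase, 2.33-fold (2.10 to 2.58) and VAPA 2.10-fold (1.84 to 2.40). SH3PXD2A had 69 reads in H446 and none listed in SHP77, at least 18.7-fold higher. NOTCH1, with 5 reads in H446 and none listed in SHP77, was under the minimum. The list median was -1.33, at percentile 6.56 of random lists. These are sums over all junctions of a gene and say nothing of any one published circRNA.

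Among 9 measured genes of region 8q24 around MYC, PVT1 was higher in H446, SQLE (4.42-fold) and NSMCE2 (3.27-fold) were higher in SHP77, and 6 were not different, including ASAP1 with 539 and 522 reads, EFR3A with 142 and 69 and DERL1 with 39 and 61 in H446 and SHP77. The median was 0.25, at percentile 65.5.

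Host genes of the Hippo pathway were higher in H446 in 6 cases, higher in SHP77 in 3 and not different in 7 of 16. TEAD1, a transcription factor that binds YAP1, was 3.97-fold higher in H446 (95% interval 3.10 to 5.13), AMOTL1 4.89-fold, WWC2 3.75-fold and WWC1 3.26-fold. PTPN14 was at least 5.70-fold higher in H446. STK3, the MST2 kinase gene, was 3.74-fold higher in SHP77 (3.14 to 4.49), TAOK3 7.37-fold (2.53 to 29.2) and MOB1B at least 8.19-fold. FAT1 and STK4, with ratios of 1.49 and 1.71 toward H446, did not reach 2-fold. The median was -0.58, at percentile 14.7. In the Notch list, NCOR1 was 3.73-fold higher in SHP77 and ADAM10, a protease that cleaves Notch receptors, 8.14-fold higher in H446 (2.53 to 41.7). MIB1 was among the 5 of 7 not different, and the median was -0.15 at percentile 49.9.

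Drug transport host genes were higher in H446 in 4 cases, higher in SHP77 in 1 and not different in 3 of 8. ABCC1, which encodes the multidrug resistance protein MRP1, had 297 reads in H446 and 42 in SHP77, a 5.76-fold difference (95% interval 4.16 to 8.16). SLC22A3, an organic cation transporter gene, had 74 and 2 reads, a 30.1-fold difference (8.05 to 253). SLC31A1, the copper transporter gene, was 3.12-fold higher in H446 (1.24 to 9.37) and ABCC3 at least 5.43-fold. ABCA3, a lipid transporter gene, was at least 28.2-fold higher in SHP77. The copper pump gene ATP7A had 51 and 36 reads and ABCC4 had 42 and 41 reads in H446 and SHP77, neither of them different. The median was -0.88, at percentile 13.3.

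DNA repair and platinum response host genes were higher in H446 in 9 cases, higher in SHP77 in 3 and not different in 14 of 26. FANCL, the ubiquitin ligase of the Fanconi anaemia pathway, had 917 reads in SHP77 and 290 in H446, 3.88-fold higher in SHP77 (95% interval 3.40 to 4.45). The damage kinase gene ATM was 2.64-fold higher in SHP77. Toward H446, ERCC6, of transcription-coupled repair, was 5.97-fold higher (3.47 to 11) and the helicase gene BRIP1 2.69-fold higher (1.77 to 4.19). RIF1 was at least 3.16-fold higher and the translesion polymerase gene POLH 4.61-fold (1.33 to 24.6). FANCD2 was 3.53-fold (1.42 to 10.5) and FANCI 2.85-fold (1.11 to 8.63) higher in H446. FANCB was 2.68-fold (1.11 to 7.38) and FANCC 2.25-fold (1.17 to 4.63) higher there. REV1, MSH3 and PRKDC were not different. The median was -0.34 at percentile 17.9, while the summed reads went the other way, with 6868 RPM in H446 and 9407 RPM in SHP77. That direction rests on FANCL, since without it, a sum chosen after seeing the data, they were 5518 RPM in H446 and 4163 RPM in SHP77. Of 6 measured apoptosis host genes, DIABLO was at least 8.60-fold higher in SHP77 and the other 5, including BIRC6, BCL2L13, BIRC2 and APAF1, were not different. Their median was 0.11, at percentile 50.3.

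Receptor kinase, PI3K and MAPK host genes were higher in H446 in 9 cases, higher in SHP77 in 4 and not different in 9 of 22. Besides PTK2 and MET, RICTOR, a subunit of mTOR complex 2, was 6.64-fold higher in H446 (95% interval 5.32 to 8.37) and the receptor gene IGF1R 4.84-fold higher (3.87 to 6.11). ERBB2 was 4.89-fold (2.04 to 14.2) and PIK3C2A 4.48-fold (2.26 to 9.85) higher in H446. ERBB4 was 3.34-fold (1.64 to 7.47) and PIK3CB 2.24-fold (1.13 to 4.76) higher there. INSR, with 2 reads in H446 and 18 in SHP77, was 11.1-fold higher in SHP77 (2.65 to 98.2). SOS2 was 4.76-fold (2.71 to 8.84) and BRAF 2.83-fold (1.43 to 5.92) higher there. MAP2K4, with 132 reads in H446 and 208 in SHP77, was 1.94-fold higher in SHP77 (1.55 to 2.43) and missed only the 2-fold minimum. The median was -0.12, at percentile 40.8. In the WNT list, TCF4, a neuronal transcription factor gene whose symbol is shared with an older name of a WNT effector, was at least 32.4-fold and TNKS 3.33-fold higher in SHP77. CTNNB1, which encodes beta-catenin, was 3.13-fold higher in H446. LRP5, LRP6, AXIN1 (1.97-fold toward H446) and GSK3B were among the 8 not different, and the median was -0.28 at percentile 32.7.

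Among 37 measured chromatin modifiers, 7 were higher in SHP77, 10 were higher in H446 and 20 were not different. In SHP77, SETD3, a list member although it encodes a histidine methyltransferase of actin, was 2.89-fold higher. EZH2 was 3.09-fold (95% interval 2.57 to 3.74) and SUZ12 2.81-fold higher there. HDAC9 was at least 17.2-fold and DNMT3A at least 9.42-fold higher in SHP77. DNMT1 was 7.37-fold (3.08 to 21.4) and DNMT3B 2.73-fold (1.19 to 6.81) higher, so all 3 measured DNA methyltransferase genes were higher there. In H446, NSD2 was 5.73-fold higher (4.61 to 7.18), NSD1 at least 7.0-fold, KDM6A 16.3-fold (6.12 to 61.2) and PBRM1 8.96-fold (2.20 to 78.6). HDAC4 was 3.66-fold, KDM5A 3.33-fold, CREBBP 3.24-fold, ATRX 3.18-fold, ASXL2 2.44-fold and EED 2.13-fold higher there. ASXL1 and KDM1A were not different. The median was -0.12, at percentile 47.4, and the summed reads were 24265 RPM in H446 and 26065 RPM in SHP77, or 22081 and 19746 RPM without SETD3, a sum chosen after seeing the data.

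Of 9 measured regulators of back-splicing, 2 were higher in each library. ADARB1, which encodes an RNA editing enzyme, had 1159 reads in H446 and 106 in SHP77, an 8.90-fold difference (95% interval 7.29 to 11). QKI, which encodes an RNA-binding protein that promotes circRNA formation, had 49 reads in H446 and none listed in SHP77, at least 13.3-fold higher. HNRNPM was 2.40-fold higher in SHP77 and ADARB2 at least 8.60-fold. HNRNPC and METTL3 were not different. The median was -0.55, at percentile 24.7. In the cell cycle and MYC list, RBL2, a relative of the retinoblastoma gene, was 5.32-fold higher in SHP77 (2.14 to 15.8) and CDC27, at the limit of 2-fold, 2.0-fold higher (1.1 to 3.75), a call lost with TMM or DESeq2 factors and with adjustment over the list alone. MGA, AURKA, CDK13 and CHEK2 were among the 6 of 8 not different, and the median was 0.28 at percentile 72.5.

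Hosts widely described as sources of circRNAs split evenly, with 8 higher in SHP77, 7 higher in H446 and 12 not different of 27. In SHP77, MBOAT2 was 8.67-fold higher (95% interval 6.43 to 11.9), CORO1C 3.08-fold, N4BP2L2 2.97-fold, SETD3 2.89-fold, LPAR1 2.16-fold, ANKRD17 2.08-fold and ZKSCAN1 2.05-fold, and RMST at least 11.1-fold. In H446, FNDC3B was 14.0-fold higher (9.65 to 20.9), UBAP2 2.47-fold, HIPK3 2.35-fold and CAMSAP1 2.30-fold. MLLT3 was 2.29-fold (1.12 to 5.06), PICALM 2.24-fold and FBXW7 2.15-fold (1.14 to 4.31) higher there. XPO1 and CDYL, with ratios of 1.26 and 1.80 toward H446, missed only the 2-fold minimum. The median was -0.28, at percentile 35.4. For markers of other cell types, the haematopoietic list had 1 measured member, LYN, with 28 reads in H446 and none listed in SHP77, at least 3.80-fold higher. No endothelial marker reached the minimum, and ERG had 13 reads in H446. Adjusted over the list alone, the counts of every list were as given, except that chromatin modifiers had 8 higher in SHP77 and 10 higher in H446, and the cell cycle list 1 and 0. Random lists were matched on reads, and their percentiles describe these 2 libraries.

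The fourth comparison asked whether the same junctions were used within a host gene. TUSC3 used different leading junctions in each line. Its junction at chromosome 8, 15588175 to 15605974, took 66.7% of 234 TUSC3 reads in SHP77 (exact 95% interval 60.2 to 72.7%) and was not listed in H446, where the junction at 15508206 to 15531345 had 113 of 151 reads and was itself not listed in SHP77. PRKAR1B, which encodes a regulatory subunit of protein kinase A, had 78.3% of its reads in H446 (73.0 to 83.0%) from the junction at chromosome 7, 716866 to 751164, which was not listed in SHP77. PDCD11 had 97.8% of 91 reads in H446 at chromosome 10, 105197772 to 105198565, and all of its 66 reads in SHP77 at 105199503 to 105200607. SMYD3 had 46.3% of 520 reads in SHP77 at chromosome 1, 246021798 to 246027188, against 3.0% of 233 reads in H446. TTC33 had all of its 75 reads in H446 at chromosome 5, 40728447 to 40747121, and 11.4% of 70 reads there in SHP77 (5.07 to 21.3%). Of 1131 host genes with at least 2 circRNAs and at least 20 reads in each library, 438 (38.7%) differed in the share of the leading junction by Fisher's exact test with Benjamini-Hochberg adjustment, and 777 (68.7%) had the same leading junction in both libraries. Of the 438, another junction led in 192.

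The fifth comparison described where in the genome the reads came from. Chromosome 21 took 1.52% of back-splice reads in H446 and 0.850% in SHP77, 1.79-fold higher in H446 (95% interval 1.68 to 1.91). ADARB1, with 1159 reads in H446 and 106 in SHP77, lies on this chromosome, as do USP25 and NRIP1. Of its 35 host genes, 11 were higher in H446 and 6 were higher in SHP77, with a median log2 ratio of -0.08. Chromosome 9 was 1.63-fold and chromosome 5 was 1.55-fold higher in H446, where the CEP72 host gene alone had 1894 reads against 38. Chromosome 7 took 3.93% in H446 and 6.32% in SHP77, 1.61-fold higher in SHP77 (1.57 to 1.66), and holds RAPGEF5, ABCA13 and DGKB. Chromosomes 20 and 14 were 1.54-fold and 1.5-fold higher in SHP77. On chromosome 8, 68 of 140 host genes were higher in SHP77 and 17 were higher in H446, although the ASPH circRNA lies there. Without the 20 most abundant circRNAs of either library, the chromosome 21 ratio of SHP77 over H446 went from 0.558 to 0.781.

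**Figure D3:**
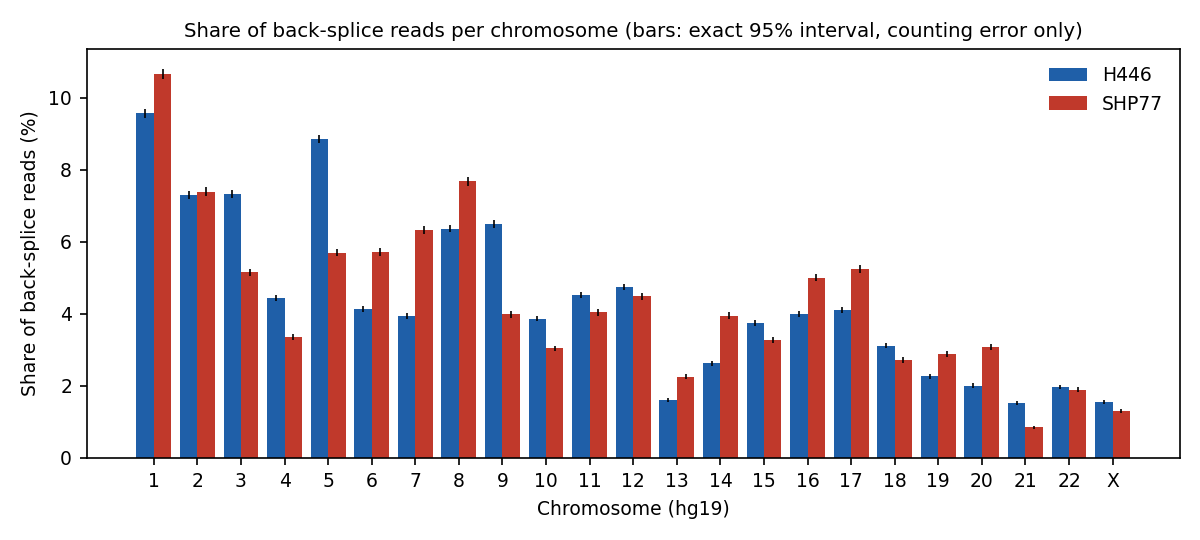
Share of back-splice reads per chromosome in percent, with H446 and SHP77 side by side, 1 library each, and error bars giving the exact 95% interval for counting error. Chromosomes 5 and 9 take larger shares in H446, and chromosomes 7 and 14 take larger shares in SHP77.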

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

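Alternatives with a circRNA not listed counted as 1 read, with only items listed in both libraries, with list members at their bound, and with sums without the most-read member were chosen after seeing the data. No called host gene or circRNA was called in the opposite direction under any alternative run. With only the leading junction, 1011 of the 1161 called host genes that could be tested kept their call. With only circRNAs listed in both, 1288 of 1432 called circRNAs did. TMM and DESeq2 factors moved the median log2 ratio over all items by less than 0.1, and the authors' RPM repeats the scaling by totals and gives no separate value. Counts moved with the read minimum, by construction. With at least 5 reads the catalogues held 8126 (H446) and 6886 (SHP77) circRNAs, of which 3659 were shared, and with at least 10 reads 4318 and 3603. CircRNAs higher in SHP77 and H446 were 2741 and 2477 without a minimum, where the larger count passed to SHP77, and 953 and 1067 with at least 20 reads. With only circRNAs listed in both they were 662 and 626. Host genes higher in SHP77 and H446 were 396 and 473 with at least 50 reads, 1326 and 1189 without a minimum, and 427 and 462 at 4-fold. Host genes that differed in junction use were 245 with at least 50 reads in each library. With only circRNAs listed in both, 9 chromosomes passed the fixed minimum ratio between their shares, against 14 with all circRNAs. With only members listed in both, the neuroendocrine median was 1.14 (percentile 91.5, no longer beyond the upper limit of random lists), since its 7 unlisted members were left out, the mesenchymal median was -2.51 (percentile 1.02, still beyond the lower limit) over 3 members, and the epithelial median stayed at 1.94 with its percentile at 98.2. With only the leading junction, the log2 ratio of 6 named host genes changed sign, none of them a called difference, to -0.33 for ASAP1, -0.31 for BIRC6, 0.23 for GSK3B, 0.46 for MSH3, 0.38 for PRKDC and 0.92 for STXBP5L, and the cause was not tested. Without the most-read member, the log2 ratio of summed reads changed sign for the 3 sums given, to -0.41 for DNA repair, -0.16 for chromatin modifiers and -0.34 for phosphodiesterase genes, and also for drug transport, regulators of back-splicing and channel genes, whose sums are not given. Of the 159 host genes taken by the naming rule, 48 lost the call at 4-fold, and CDC27 lost it with TMM and with DESeq2 factors. When a circRNA not listed counted as 1 read, 8 lost it, ANKRD17, CDC27, FANCI, MLLT3, NSMCE2, PIK3CB, UNC13B and WWC1. With only the leading junction 8 lost it, among them BRIP1, CDC27, EED, ERBB4, KDM5A, MLLT3 and TJP1. The 16 circRNAs with the largest differences by the fixed rule kept their call under every alternative that could test them, and 1 of them, PDE4B, is listed in both libraries. No paired analysis was possible because each line has a single library, and for the same reason no library could be left out.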

Other observations

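The gene groups, the genes named in them, the 10 Mb windows singled out, the sum without the most-read member, the neighbour distances of 5 and 20 Mb, and the tests of a rearranged locus and of a filter were chosen after the values were seen; the other tests were set beforehand. Genes of the adhesion G protein-coupled receptor and teneurin families, some of which act in neuronal wiring, were mostly higher in SHP77. Of 6 measured, 4 were higher in SHP77 and 1 was higher in H446. ADGRL3, with 159 reads in SHP77 and none listed in H446, was at least 16.3-fold higher, ADGRB3 at least 14.9-fold and TENM1 at least 17.8-fold, while ADGRE5, also named CD97 and known from leukocytes, was at least 7.87-fold higher in H446. Among 9 voltage-gated and related channel genes, 6 were higher in SHP77, with CACNA2D1 at least 12.4-fold and SCN8A, with 61 reads, among them, and 3 were higher in H446, with KCNH5 at 93.8-fold (95% interval 36.4 to 346) and KCNH1 at least 13.5-fold. CACNA2D3 was at least 5.94-fold higher in H446. Collagen genes were higher in H446 in 4 of 5 cases, with COL25A1 at least 15.5-fold and COL12A1 and COL4A5 with 35 reads each there and none listed in SHP77, against COL22A1, at least 26.4-fold higher in SHP77. The integrin gene ITGB5 was at least 8.96-fold higher in H446.

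Phosphodiesterase genes all differed, 4 higher in SHP77 and 7 higher in H446 of 11. Besides PDE4B, PDE1C was at least 20.3-fold and PDE8A 3.68-fold higher in SHP77, while PDE3A was 11.4-fold (95% interval 7.57 to 17.8) and PDE4D 2.55-fold higher in H446. The median was -1.34 although the summed reads were higher in SHP77, 12329 RPM against 6533 RPM. That direction rests on PDE4B, the most-read member, since without it the sums were 5158 RPM in SHP77 and 6524 RPM in H446. Solute carriers divided evenly, 14 higher in SHP77 and 15 higher in H446 of 43. The host genes of both subunits of the cystine transporter had more back-splice reads in H446, SLC7A11 at least 8.96-fold and SLC3A2 9.36-fold (3.42 to 35.8). Zinc finger genes (13 higher in SHP77, 11 higher in H446, 46 measured) and proteasome genes (2 and 4, 11 measured) went both ways. PSMA7, with 175 reads in SHP77, was at least 71.6-fold higher there, and PSMC3 at least 18.5-fold higher in H446. The long intergenic RNAs LINC00355 and LINC01121 were the 2 measured of their kind, both higher in SHP77.

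The lines shared 5601 circRNAs, fewer than in draws with counting error of reads alone. In 100 pairs of libraries drawn from the pooled profile at the real totals, 11163 to 11387 circRNAs were shared, which argues against sampling of independent reads as the whole cause. The draws cover counting error only. Their profile holds only circRNAs listed in at least 1 library, which can raise the number shared in the draws. The size of this effect was not tested. A sampling of fewer molecules before amplification was not tested either and stays open. CDYL2 and SOBP show the extreme of this difference. That the lines make different circRNAs is a hypothesis that stays open beside such a sampling of molecules and a difference in preparation, since each line has 1 library.

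In all, 128 host genes had at least 50 reads in 1 library and none listed in the other, 59 in H446 and 69 in SHP77, where none arose in 100 drawn pairs, which argues against sampling of independent reads as the cause and leaves a sampling of molecules before amplification open. A rearranged locus that gives a single junction is argued against as the cause in most of them, since the leading junction took a median of 66.6% of reads over all 128 (95% interval of the median 59.7 to 72.7%), under the limit of 90% set for a single junction. For a part of them this cannot be decided. VAMP3, ARF3 and PSMA7 were among the 30.5% with a leading junction of 90% or more. Sets of host genes listed in both libraries and matched on reads had a median of 18.8% (12.5 to 25.8%). The sets were not matched on number of junctions. A host gene with few junctions is more easily unlisted as a whole, so the excess may come from the selection. These values concern only a rearrangement that gives a single junction. Other changes of a locus, such as its loss in 1 line, were not tested. A filter in the making of the lists also stays open, because among circRNAs with at least 100 reads in 1 library, 58 were not listed in the other and 18 were listed there with 2 to 10 reads, and a circRNA that a line does not make would look the same. With 1 library per line, preparation and line cannot be told apart, and no biological explanation such as the labelled chemosensitivity was tested.

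Neighbouring host genes had a weak tendency to differ in the same direction. The Spearman correlation of log2 ratios between next neighbours was 0.16 across host genes, above the highest of 10000 shuffles, 0.066 (permutation p = 0.0001, the smallest they can give), which argues against chance order. Reads shared between overlapping genes are argued against by 0.15 for neighbours at least 100 kb apart. Gain or loss of chromosome segments in 1 line is a candidate explanation, as the correlation was 0.12 for neighbours at least 1 Mb apart (highest shuffle 0.079) and 0.10 for those at least 5 Mb apart (highest shuffle 0.073). At least 20 Mb apart it was 0.055, above the upper limit of the 95% range of shuffles, 0.040, and under the highest, 0.077 (permutation p = 0.0056). Shared regulation of a region would give the same and copy number was not analysed here. Examples were picked for their one-sided counts from 242 windows of 10 Mb with at least 5 host genes, and do not describe the typical window. In the first 10 Mb of chromosome 5, 9 of 11 host genes were higher in H446. They included CEP72, LPCAT1 (13.0-fold) and SRD5A1 (at least 14.1-fold). In the first 10 Mb of chromosome 12, 9 of 11 were higher in H446, among them ERC1 (5.67-fold). On chromosome 8 from 70 to 80 Mb, 5 of 5 were higher in SHP77, among them STAU2 (5.29-fold) and NCOA2 (4.12-fold).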
